A study of Mus musculus with 27 samples.

How the data were processed

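RNA was profiled in 21 tumours on Affymetrix mouse arrays and DNA in 6 tumours on Agilent arrays that also held liver DNA. The RNA values deposited by the authors are linear probe-set intensities, made with MAS5 per the submitters' processing notes, with version and scaling target not given in the sources used here. Array means lay between 221.4 and 256.4. The DNA files are scanner output of Feature Extraction 9.5.3.1 with positions of build mm8, per the file headers, and the processed intensities used from them were background-subtracted and dye-normalized by that program. Tumour DNA was in the Cy5 and liver DNA in the Cy3 channel per the labels. The authors' value table of these arrays held log10 ratios in the same direction, and correlated at 0.9996 or more with the scanner log ratios of each array, with column medians between -0.0109 and -0.00158. The deposited log10 scale was converted to log2 for the alternative that used it.

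For RNA, an offset of 4, from the 20th percentile of signal, was added before taking log2 of the deposited intensities, which understates changes of dim probe sets. Fold changes are on that scale. A probe set entered if it reached its array's 40th percentile on at least 2 arrays, and 64 control probe sets were left out, which left 32842 of 45101. One linear model over 8 groups was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over the probe sets of a comparison. All such tests were two-sided with a threshold of 0.05 on the adjusted p. The model had 13 residual degrees of freedom. No 2 arrays held identical values, and the highest correlation between arrays was 0.9812.

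The design fixed before the data were examined called for 1 probe set per gene. The tables used here do not pair probe sets with genes, so each probe set was tested by itself, and the counts are of probe sets. For the same reason the tests of 23 gene lists on expression, the markers of other cell types among them, and the test of expression inside DNA gains were not made. The rule for named genes took a fixed set of genes, the largest changes past the threshold whose values did not overlap between the sides, and members of the lists. For RNA only 2 rising and 2 falling probe sets are named, the largest of 214 such candidates in the mean of 3 times, and using that 1 comparison for all others was decided after seeing the data. Their values in comparisons that reuse those arrays are not independent of that choice. For DNA the rule took 16 fixed genes and, per resistant tumour, the 5 segments with the largest mean log2 among those not shared with vehicle tumours, with up to 6 genes each.

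For DNA, log2 ratios of the processed signals were centred on each array's autosomal median, without loess or quantile normalization. Control spots and outliers were left out and probes of 1 name averaged, which left 233011 probes with values on all arrays. Each array was segmented by penalised least squares with a penalty of 3 times the usual per breakpoint, and a segment was called at a mean of 0.3 or more in size over at least 5 probes. A segment was taken as not shared when calls of the same sign in vehicle tumours covered under 50% of its length. Windows of 1 Mb with at least 5 probes were tested with limma. Probes were named by the files, and the names table of assembly GRCm38.p6 served for names and gene order, with none of its coordinates. Between 99.8% and 99.9% of probes were well above background in both channels. The SD of neighbouring probes was 0.132, 0.198 and 0.176 in vehicle and 0.318, 0.28 and 0.462 in resistant tumours, so smaller changes were detectable in vehicle tumours.

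The methods were tested on simulated data. With 200 of 32842 probe sets changed by 1 on the log2 scale, the RNA model recovered 40.5% at 4 h, 16% at 48 h and 60% for resistant against vehicle. With changes of 2 it recovered 82.5%, 72% and 93%. The window test recovered 100% of 200 windows of 2551 shifted by 0.3. That shift was equal in each resistant array, so the figure does not cover changes present in only some tumours. Segmentation at the noise of the 160 mg/kg/day array found 100% of planted steps of 0.4 over 300 probes and 0% over 100 probes. The number of arrays limits the precision of all comparisons. Alternatives to the offset, scaling, filter, trend, weights, samples, block, window, threshold and penalty were computed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0 were used.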

Results

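The series followed medulloblastoma grown from tumours of Ptch+/-p53-/- mice. Ptch1 restrains the receptor Smo, through which Hedgehog signalling acts. The tumour cells were grafted under the skin of nude mice, which were given vehicle or NVP-LDE225, an antagonist of Smo. Dosing began about 10 days after implantation. Resistant tumours were seen after 13 units of continuous dosing, with the unit missing from the label, and were collected on day 26 of treatment. RNA was measured on 21 one-colour arrays, 1 tumour per array. The 8 vehicle tumours were taken at 4 h (n = 3), 16 h (n = 3) and 48 h (n = 2), and the 8 tumours still sensitive to LDE225 were taken at the same times (n = 3, 3 and 2) at 20 mg/kg/day given once a day. The 5 resistant tumours had received 20 mg/kg/day (n = 2) or 160 mg/kg/day (n = 3), in 2 daily doses. DNA was measured on 6 two-colour arrays against liver DNA, for 3 vehicle tumours and for 1 resistant tumour each at 40, 80 and 160 mg/kg/day. The labels of that last tumour disagree: its status, treatment and dose read resistant, LDE225 and 160 mg/kg/day, while its title and source name carry the word vehicle, and it was grouped by the 3 former labels. No tumour was stated to be in both sets.

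The first comparisons asked how quickly the transcriptome of sensitive tumours answered the drug. At 4 h, 34 of the 32842 probe sets tested had changed (limma, adjusted p below 0.05), of which 31 fell and 3 rose. At 16 h the number was 4727, with 2584 higher and 2143 lower, and at 48 h it was 7462, with 3817 higher and 3645 lower. The early falls recurred later: 27 of the 31 probe sets that fell at 4 h also fell at 16 h, where 2.02 would be shared by independent lists, and 26 of the 31 fell at 48 h, where 3.44 would be. Of the 2143 that fell at 16 h, 1327 fell at 48 h (238 by independent lists), and of the 2584 that rose, 915 rose again (300 by independent lists). These comparisons had no arrays in common. Changes of at least 2-fold numbered 31 at 4 h, 1634 at 16 h and 4336 at 48 h. The count at 4 h depended on single tumours: it was 2, 4 and 4 without vehicle tumours 1, 2 and 3, and 10 and 5 without LDE225 tumours 1 and 2. The count at 16 h was 2846 without vehicle tumour 1 and 2881 without LDE225 tumour 3, and that at 48 h was 2862 without vehicle tumour 3, 4495 without LDE225 tumour 1 and 4123 without LDE225 tumour 2.

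Averaged over the 3 times, LDE225 changed 7366 probe sets, 3992 upward and 3374 downward. The probe sets are given by identifier because the gene tables used here do not pair them with genes. Among the 214 probe sets that passed and whose values did not overlap between the sides, 1437933_at fell with a log2 change of -3.53 (standard error 0.29, limma, adjusted p = 1.5e-07). Its signal averaged 204 ± 37.3 (SD, n = 3) in vehicle tumours at 4 h and 50.6 ± 20.9 (n = 3), 13.5 ± 10.4 (n = 3) and 2.55 ± 2.62 (n = 2) in treated tumours at 4 h, 16 h and 48 h. The last of these lies below the offset of 4, which therefore sets the size of the fall: it was -4.02 with an offset of 1 and -2.30 with one of 27. The brighter 1427130_x_at had a log2 change of -3.40 (standard error 0.29, limma, adjusted p = 2e-07), from 3270 ± 457 (n = 3) in vehicle tumours at 4 h to 105 ± 14.4 (n = 2) in treated tumours at 48 h. The largest rises among these 214 were those of 1452114_s_at, by a log2 change of 2.20 (standard error 0.35, limma, adjusted p = 0.00014), and 1455436_at, by 1.46 (standard error 0.28, limma, adjusted p = 0.001). The signal of 1452114_s_at was 195 ± 10.8 (n = 3) in vehicle tumours at 4 h and 1890 ± 171 (n = 3) in treated tumours at 16 h. That of 1455436_at was 144 ± 9.12 (n = 2) and 620 ± 17.8 (n = 2) in vehicle and treated tumours at 48 h. Without vehicle tumour 3 of 48 h the count for the mean of 3 times was 4797.

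The effect of the drug differed between times in a direct test. Between 48 h and 4 h it differed for 4204 probe sets (2005 with a higher and 2199 with a lower log2 effect at 48 h), and between 16 h and 4 h for 1258 (544 higher, 714 lower). The fall of 1427130_x_at deepened between 4 h and 48 h by a log2 difference of -3.22 (standard error 0.74, limma, adjusted p = 0.0074), and it passed with each of the 3 offsets. For 1437933_at the difference was -2.83 (standard error 0.74, limma, adjusted p = 0.017), but -1.17 with an offset of 27, where it did not pass (limma, adjusted p = 0.16). The effect on the 2 rising probe sets did not pass the test of a difference between 48 h and 4 h. The 48 h contrast had 2 tumours on each side at 48 h, so leaving out 1 of them left a lone tumour in its group. The count fell without vehicle tumour 3, LDE225 tumour 1 or LDE225 tumour 2 of 48 h, but rose without vehicle tumour 1. The 16 h contrast gave 827 and 694 without vehicle tumours 1 and 3 of 4 h, 782 without vehicle tumour 1 of 16 h, 677 without LDE225 tumour 2 of 4 h and 599 without LDE225 tumour 3 of 16 h.

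**Figure D1:**
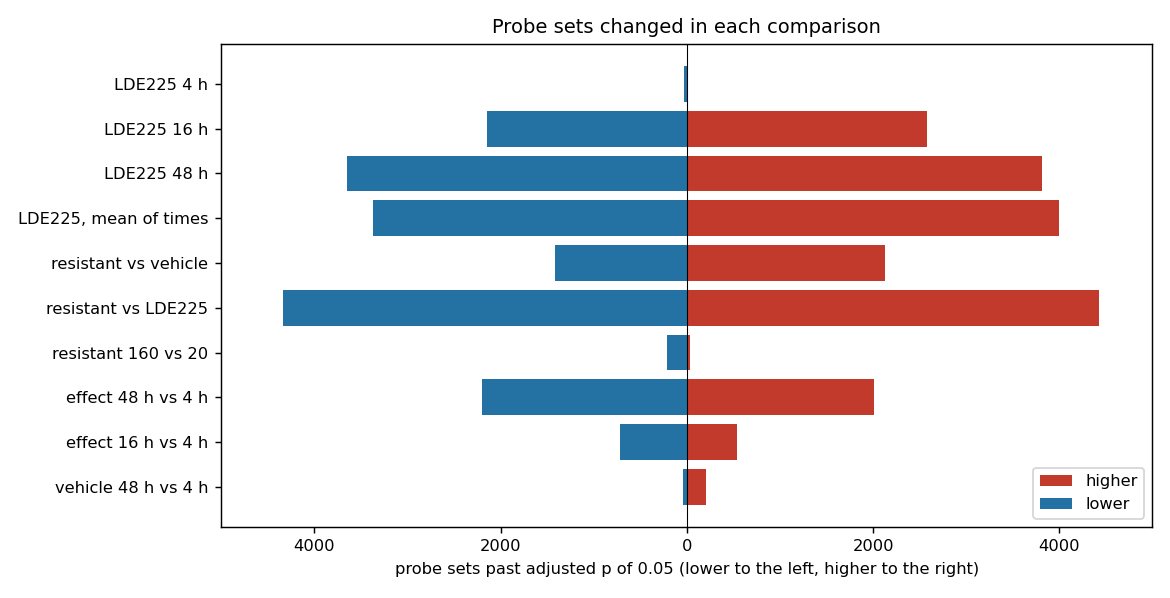
Numbers of probe sets past an adjusted p of 0.05 (x axis) in each of 10 comparisons of the 21 RNA arrays (y axis), with rises drawn to the right in red and falls to the left in blue. The bars for LDE225 grow from 34 probe sets at 4 h to 4727 at 16 h and 7462 at 48 h.

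Resistant tumours were then compared with vehicle tumours, which asks how tumours growing under the drug differ from untreated ones. Of the probe sets tested, 3540 differed, with 2128 higher and 1412 lower in the 5 resistant tumours, and 798 differed by at least 2-fold (644 higher, 154 lower). The probe set 1437933_at, which had fallen under the drug, stood at 136 ± 20.8 (SD, n = 2) at 20 mg/kg/day and 290 ± 245 (n = 3) at 160 mg/kg/day, and its log2 difference from vehicle, -0.11 (standard error 0.34, limma, adjusted p = 0.87), did not pass. The log2 difference of 1455436_at, which had risen under the drug, was -0.86 and did not pass (limma, adjusted p = 0.097). In contrast, 1427130_x_at was on average lower by -1.78 (standard error 0.33, limma, adjusted p = 0.002), and 1452114_s_at higher by 1.84 (standard error 0.40, limma, adjusted p = 0.0057). The resistant tumours were scattered for both: 1427130_x_at stood at 1010 ± 1060 (n = 2) and 1200 ± 232 (n = 3) at 20 and 160 mg/kg/day, and 1452114_s_at at 1170 ± 1110 (n = 2) and 798 ± 625 (n = 3). The choice of vehicle arrays moved the count: against the 2 vehicle tumours of 48 h it was 441 (274 higher, 167 lower), against those of 4 h 2548 and against those of 16 h 4050, the last 2 sets chosen after seeing the data. The ratio of the 3′ to the 5′ actin probe set, a sign of RNA integrity or of a labelling run, lay between 1.25 and 1.40 in the 9 arrays of 48 h and resistant tumours and between 1.53 and 1.91 in the 12 arrays of 4 h and 16 h. Without resistant tumour 2 of 20 mg/kg/day the count was 1321. No vehicle RNA array of day 26 was analysed here, so time on study and resistance went together in this comparison.

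Against sensitive tumours under the drug for 16 h or 48 h, resistant tumours differed at 8760 probe sets, 4429 higher and 4331 lower. The dose schedules of these groups also differed. The named probe sets had been picked for extreme values in the treated arrays used here, which favours large differences. The level of 1437933_at was higher in resistant tumours by a log2 difference of 4.22 (standard error 0.37, limma, adjusted p = 3.4e-07, and 2.60 with an offset of 27) and that of 1427130_x_at by 2.48 (standard error 0.37, limma, adjusted p = 7.2e-05). The probe set 1455436_at was lower by -2.69 (standard error 0.36, limma, adjusted p = 2.6e-05). The difference of 1452114_s_at, -1.01 (standard error 0.44, limma, adjusted p = 0.098), did not pass. Against the treated tumours of 48 h alone, which shared the lower actin ratio of the resistant arrays, the count was 9811.

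Whether the answer to the drug was still present in resistant tumours was followed with probe sets picked from the 16 h arrays alone, a choice made after seeing the data. Of these, 924 had risen and 836 had fallen at least 2-fold at 16 h. At 48 h, 515 of the 836 (61.6%) were lower in treated than in vehicle tumours, with a median log2 change of -1.09, against 9.7% of all probe sets. In resistant tumours 45 of the 836 (5.38%) were lower than in vehicle tumours of 4 h and 48 h, with a median of -0.18, against 1% of all probe sets, and 544 (65.1%) were higher than in treated tumours of 48 h, against 13.4% of all. Of the 924 that had risen, 392 (42.4%) were higher at 48 h, against 10.1% of all, and 109 (11.8%) were higher in resistant than in vehicle tumours, against 2% of all. In resistant tumours at 20 mg/kg/day 139 of the 924 (15%) were higher than in vehicle tumours, against 1.93% of all. At 160 mg/kg/day 25 (2.71%) were, against 0.633% of all. Relative to vehicle tumours of 4 h, the mean log2 rise minus the mean log2 fall over these sets was 2.53 ± 0.0672 (SD, n = 2) in treated tumours of 48 h, 0.365 ± 0.0529 (n = 3) in treated tumours of 4 h and 0.55 ± 0.419 (n = 5) in resistant tumours. The mean of resistant tumours minus that of treated tumours of 48 h was -1.98, with an exact two-sided permutation p of 0.0476, the smallest that 21 splits can give, which did not pass after adjustment over 30 such tests (0.119). Their difference of 0.429 from the 5 vehicle tumours of 4 h and 48 h did not pass either (exact two-sided permutation p = 0.0794, adjusted 0.13). Within the resistant group the value was 0.735 and 1.193 at 20 mg/kg/day and 0.194, 0.403 and 0.225 at 160 mg/kg/day. Vehicle tumours of 4 h and 48 h averaged 0.121 and reached 0.502. The exact two-sided permutation p for the 2 doses was 0.1, the smallest that 10 splits allow.

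**Figure D2:**
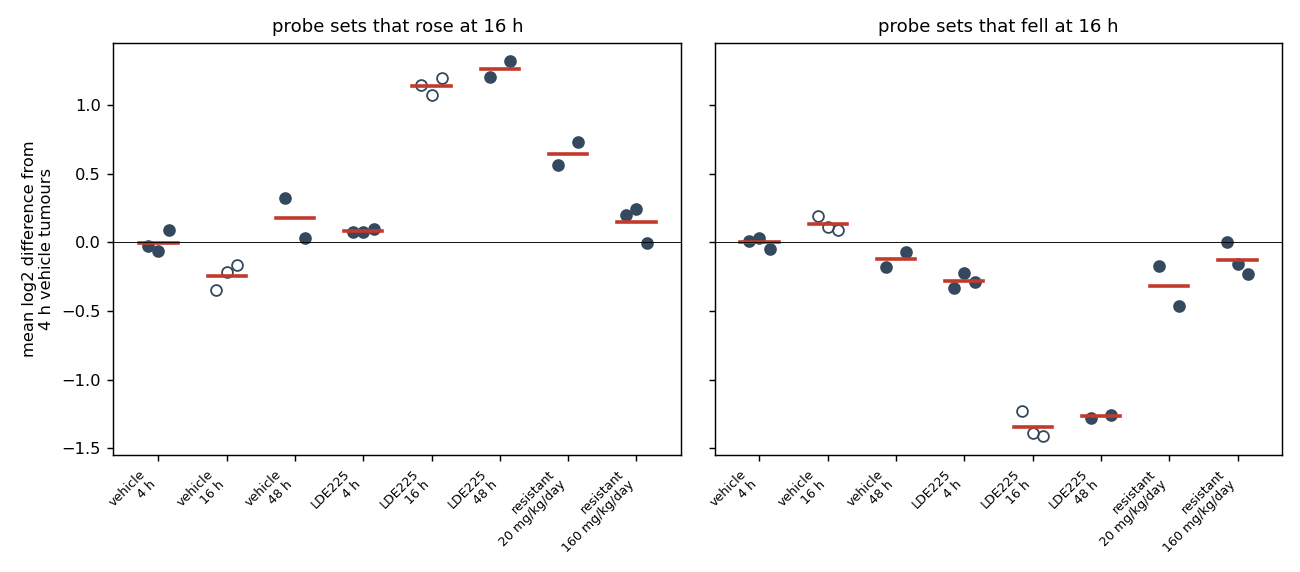
Mean log2 difference from the vehicle tumours of 4 h (y axis) of the 924 probe sets that rose (left) and the 836 that fell (right) at 16 h, for each of the 21 arrays by group (x axis). Points are tumours, red bars are group means, and hollow points mark the 16 h arrays on which the sets were picked. Rises averaged 1.26 in treated tumours of 48 h and 0.347 in the 5 resistant tumours, and falls averaged -1.27 and -0.203.

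Between the doses, 254 probe sets differed, with 38 higher and 216 lower at 160 than at 20 mg/kg/day. None of the 4 probe sets named above passed in this comparison. The resistant tumours at 160 mg/kg/day varied more among themselves than any other group, with a median SD of 0.354 on the log2 scale against 0.174 to 0.254 in the other 7 groups. The count was 475 and 4 without tumours 1 and 2 of 20 mg/kg/day and 1360 without tumour 1 of 160 mg/kg/day. A fit of the 5 resistant arrays by themselves called 0 probe sets in limma, with 2037 at an unadjusted p below 0.05.

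Untreated tumours also differed between harvest times. Between 48 h and 4 h, 245 probe sets changed among vehicle tumours, 207 higher and 38 lower, while the 4 named probe sets did not pass. This comparison lies across the same division in actin ratio as above. The count was 90, 113 and 64 without tumours 1, 2 and 3 of 4 h, and 38 and 7 without tumours 1 and 3 of 48 h.

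In DNA, all 6 tumours carried an extra amount of chromosome 6, whose median log2 ratio lay between 0.45 and 0.50 on every array. This chromosome holds Smo, the drug's target, with a segment mean of 0.53 to 0.56 in vehicle tumours and 0.47 to 0.53 in resistant tumours, and Ccnd2, a cyclin of the G1 phase. Chromosome 16 was broken into alternating gains and losses on all 6 arrays, with 6 to 10 gains and 7 to 12 losses in vehicle tumours. In all, 67, 39 and 55 segments were called in the vehicle tumours and 17, 46 and 24 in the resistant tumours at 40, 80 and 160 mg/kg/day. Of the latter, 6, 32 and 16 were not shared with vehicle tumours, 54 together, of which 24 were gains and 30 losses. Segments are not separate alterations, and the less noisy vehicle arrays were split more finely. The gain of chromosome 6 alone was called as 22, 12 and 16 segments in vehicle and 2, 1 and 1 in resistant tumours. The segments not shared covered 3.5, 120.9 and 126.0 Mb in gains and 207.2, 208.9 and 197.5 Mb in losses. Positions are those of genome build mm8. Each DNA profile is that of 1 tumour, so values carry the error over probes and no error between tumours.

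The resistant tumour at 40 mg/kg/day had a stepped gain at the end of chromosome 16. The mean log2 ratio was 0.90 (SD over probes 0.35, 38 probes) from 94734730 to 95009861, 1.41 (SD 0.34, 264 probes) from 95015281 to 97172966 and 2.25 (SD 0.37, 131 probes) from 97181619 to 98237087. The middle step held Erg and Ets2, transcription factors of the ETS family, and the top step held Mx1, an interferon-induced GTPase, Dscam, a neuronal adhesion receptor, and Tmprss2, a membrane serine protease. The same tumour had lost 42.6 Mb of chromosome 10, from 3002742 to 45612178, at a mean of -0.88 (SD 0.34, 3754 probes). The lost part held Perp and Sesn1, targets of p53, and Foxo3, a transcription factor inhibited by AKT. With normexp signals its mean was -0.562 and that of X -0.542. The X chromosome stood at -0.87 over its whole length, against medians of -0.23 to -0.25 in vehicle tumours, and chromosome 8 had a median of 0.23.

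The resistant tumour at 80 mg/kg/day had its highest gain on chromosome 1, from 118050387 to 122456234, with a mean of 2.05 (SD 0.45, 287 probes). This 4.41 Mb segment held 17 genes with probes, among them Tsn, Tfcp2l1, Inhbb, a subunit of inhibins and activins, and Ralb, a small GTPase. Gli2, the main transcriptional activator of Hedgehog signalling, had 0 probes under its name. In the table of gene names (GRCm38.p6, used for gene order only) Gli2 lies between Tfcp2l1 and Inhbb, and the 41 probes between these genes, from 120519632 to 121235120, had a mean of 2.28 (SD 0.42) in this tumour. The same probes had a mean of 1.20 (SD 0.54) at 160 mg/kg/day, 0.21 (SD 0.38) at 40 mg/kg/day and 0.07, 0.09 and 0.14 in vehicle tumours. A second gain on chromosome 1, from 109874205 to 111137946, had a mean of 0.90 and no gene with probes. The largest losses not shared with vehicle tumours were on X, at -0.88 from 147371768 to 152388764, with Kdm5c and Smc1a, and at -0.81 from 154237968 to 165518375, and on chromosome 10, at -0.75 from 31346398 to 34621408, with Frk, a tyrosine kinase. With normexp signals the means of these 3 losses were -0.162, -0.155 and -0.145, below the size of a call, and the highest gain was 1.356. Smaller gains covered Deptor, an mTOR inhibitor, at 0.49, Sqle, an enzyme of cholesterol synthesis, at 0.72 and Myc at 0.42, all on chromosome 15.

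The resistant tumour at 160 mg/kg/day, whose title contradicts its other labels, had a gain of chromosome 1 that included the same interval, from 107368793 to 121727135, at a mean of 0.85 (SD 0.49, 811 probes). This segment held Bcl2, an inhibitor of apoptosis, and Tnfrsf11a. The others among the 5 segments with the largest mean log2 not shared with vehicle tumours were losses on chromosome 10. One stood at -0.81 (SD 0.43, 673 probes) from 94988530 to 105261491, with Dcn, Lum and Kitl, the ligand of the receptor Kit. The rest stood at -0.80 from 122111227 to 124607611, -0.76 from 8987090 to 30864007 and -0.74 from 31330229 to 38545777. Losses outside these 5 included the end of X at -0.74 and chromosome 19 at -0.72. A loss of 76.6 Mb of chromosome 3, from 3007185 to 79629324 at -0.71, was not called in the other 5 tumours and held Pik3ca, the catalytic subunit of PI3K, Sox2, Fgf2 and Foxo1.

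**Figure D3:**
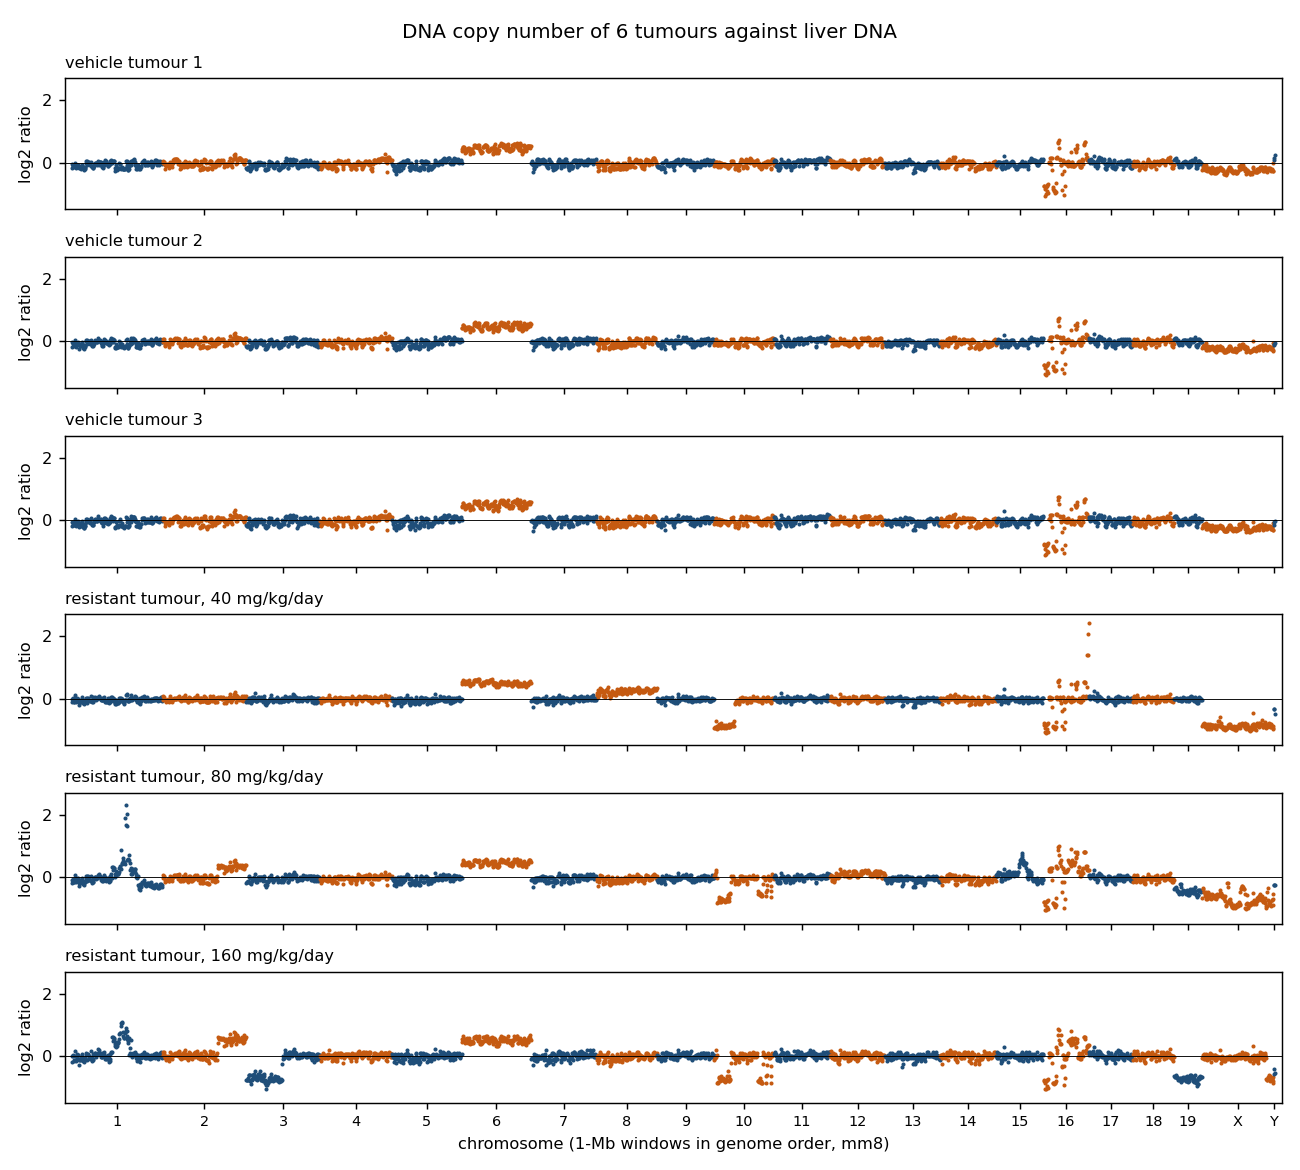
Mean log2 ratio of tumour over liver DNA (y axis) in 1-Mb windows along the genome (x axis, chromosomes in alternating colours) for the 3 vehicle and 3 resistant tumours. Every tumour shows the gain of chromosome 6, and all 3 resistant tumours show losses on chromosome 10 and at the end of X.

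Common to all 3 resistant tumours, and called as a loss in no vehicle tumour, were 3 regions. The first, 21.9 Mb of chromosome 10 from 8987090 to 30864007, had means of -0.88, -0.74 and -0.76 at 40, 80 and 160 mg/kg/day over 1928 probes. It held 86 genes with probes, including Perp and, chosen after their values were seen, Myb, Tnfaip3, an inhibitor of NF-kB signalling, and Sgk1. The second, 7.2 Mb from 31346398 to 38545777 on the same chromosome, had means of -0.89, -0.67 and -0.74 and held Frk, Hdac2, a histone deacetylase, and Marcks. The last, 15.4 Mb at the end of X from 150106682 to 165518375, had means of -0.88, -0.77 and -0.74. Its last part, from 165319759, was called as a gain of 0.96 to 1.06 in the vehicle tumours. Normexp signals were an alternative added for these regions after seeing the data. With them the means at 80 mg/kg/day were -0.14, -0.13 and -0.15, below the size of a call. Whether all 3 regions are called thus depends on the signal used for that array. Its SD over probes also shrank, from 0.31, 0.33 and 0.36 to 0.07, 0.06 and 0.08. On X the vehicle tumours stood at -0.21, -0.26 and -0.25 with normexp signals. No called gain was common to the 3. Over the 3 steps of the chromosome 16 gain at 40 mg/kg/day, the other 2 resistant tumours had no call. Their means there were still 0.23 to 0.28 at 80 and 0.32 to 0.37 at 160 mg/kg/day, against 0.07 to 0.13 in vehicle tumours. This gain was thus not shown to be absent from them. The tumours at 80 and 160 mg/kg/day had 99.1 Mb of gains and 115.6 Mb of losses in common, including chromosome 2 from 119294938 to 181918277, with Aurka, E2f1 and Bcl2l1, and most of chromosome 19. Among the 47 breakpoints of segments that the tumour at 80 mg/kg/day did not share with vehicle tumours, 12 lay within 1 probe of a breakpoint at 160 mg/kg/day (10 at the same probe), where evenly scattered breakpoints would give 0.021. The same count was 5 for the tumour at 40 mg/kg/day (0.013) and 4, 6 and 5 for the vehicle tumours (0.062, 0.037 and 0.053). Shared breakpoints as such were thus not confined to this pair. The 10 at the same probe were other sites: the median step there was 0.48 at 80 and 0.84 at 160 mg/kg/day. It was 0.08 at 40 mg/kg/day and 0.01, 0.07 and 0.05 in the vehicle tumours, which took part in choosing the segments.

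**Figure D4:**
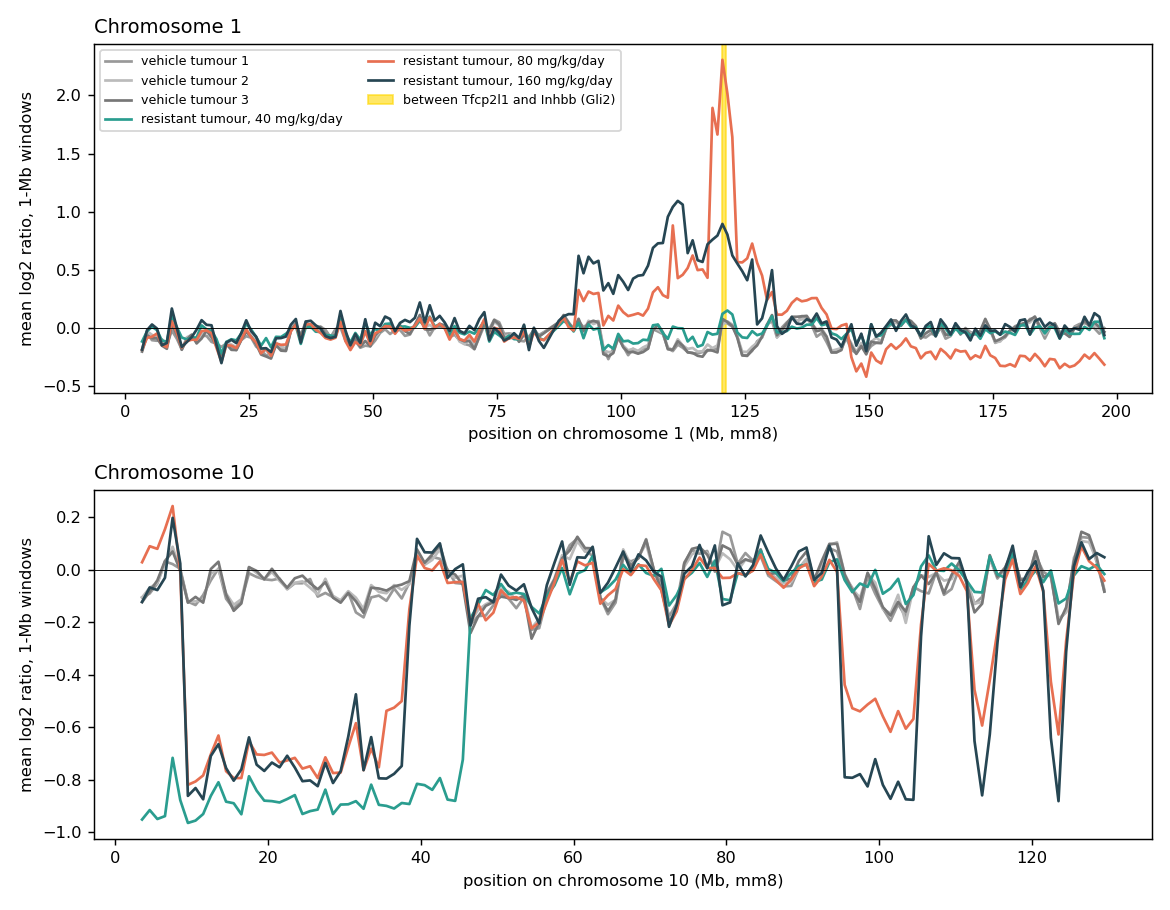
Mean log2 ratio in 1-Mb windows (y axis) along chromosomes 1 and 10 (x axis, position in Mb, mm8) for 3 vehicle tumours (greys) and the resistant tumours at 40, 80 and 160 mg/kg/day. The yellow band marks the interval between Tfcp2l1 and Inhbb, where the tumour at 80 mg/kg/day reached 2.28, and on chromosome 10 the 3 resistant tumours are lower from 8987090 to 30864007.

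A test over 2551 windows of 1 Mb found 101 that differed between the 3 resistant and 3 vehicle tumours (limma, adjusted p below 0.05), 94 lower and 7 higher. Of the 101, 42 differed by at least 0.3 on the log2 scale, all lower, with 28 on chromosome 10 and 14 on X. This size limit was chosen after seeing the data. In the first of them, chromosome 10 from 9000001 to 10000000, the means were -0.882 in resistant and -0.123 in vehicle tumours (limma, adjusted p = 0.00158). The other 59 windows differed by at most 0.168. The gain around Gli2 and the loss of chromosome 19, each absent from the tumour at 40 mg/kg/day, did not pass. The count was 32, 32 and 33 without vehicle tumours 1, 2 and 3, and 320, 475 and 210 without the resistant tumours at 40, 80 and 160 mg/kg/day. With normexp signals it was 0 in limma, with 655 windows at an unadjusted p below 0.05.

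The gene lists fixed before the data were examined could be placed on the DNA arrays for 409 of their 437 genes. Of 23 Hedgehog pathway components with probes, 1 lay in a gain not shared with vehicle tumours (Gsk3b) and 2 in such losses (Sufu, an inhibitor of Gli proteins, and Btrc) at both 80 and 160 mg/kg/day, and none did at 40 mg/kg/day. Of 19 Hedgehog targets, 3 lay in such gains at 80 mg/kg/day (Snai1, Hes1 and Nkx2-2) and 3 at 160 mg/kg/day (Bcl2, Snai1 and Nkx2-2), and none lay in losses. Among components of the PI3K pathway, not all of which are used here, Foxo3 lay in a loss at 40 mg/kg/day, Rps6kb2 in losses at 80 and 160 mg/kg/day, and Pik3ca and Foxo1 in a loss at 160 mg/kg/day, while Deptor lay in a gain at 80 mg/kg/day. Of 35 cell cycle genes, 5 lay in gains at 80 mg/kg/day (Aurka, Bub1, Pcna, E2f1 and Mybl2) and 6 at 160 mg/kg/day, where Mcm6 was added, while Kif11 lay in losses in both tumours and Ccna2 in a loss at 160 mg/kg/day. Perp, of 15 p53 targets, lay in a loss in all 3 tumours. Neighbouring genes share a segment and are not independent, and no enrichment was tested.

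Of the genes followed in every DNA profile, Gli1, Ptch1, Trp53, Mycn, Ccnd1, Igf1r, Pdgfra, Yap1 and Cdkn2a lay in no called segment on any of the 6 arrays. Mycn, Myc and Ccnd1 had 1 probe each and Gli1 had 2. The 7 probes of Ptch1 and the 3 of Trp53 need not lie in the parts deleted in this genotype, so they check nothing about it. Sufu lay in segments with means of -0.46 and -0.72 at 80 and 160 mg/kg/day, while its own 13 probes had smaller means of -0.22 (SD over probes 0.40) and -0.39 (SD 0.48). The single Myc probe stood at 0.45 at 80 mg/kg/day and -0.32 at 160 mg/kg/day.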

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

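All tests of explanations in this part, and the limits that decide them, were chosen after the results were seen. The effect of LDE225 differed between times for 4204 probe sets between 48 h and 4 h and for 1258 between 16 h and 4 h, each by a direct test of the difference. The same test gave 1427130_x_at, with a log2 difference of -3.22 between its effects at 48 h and 4 h, and 1437933_at, with -2.83. The latter value depends on the offset, since its treated signal at 48 h, 2.55, lies below the offset of 4: with an offset of 27 it was -1.17 and did not pass.

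Other splits of the same tumours were counted for each comparison with at least 3 tumours on each side. For the difference between 16 h and 4 h, 9 of 100 splits gave at least the real 1258 probe sets and the highest gave 2864, but this decides nothing about chance. All 9 kept the 16 h labels and with them the drug effect at 16 h, which the splits cannot remove, and the highest with those labels broken gave 1. For the mean of 3 times, 1 of 100 splits, the real one, reached 7366, with 6836 as the highest other. For resistant against vehicle tumours 1 of 100 reached 3540, with 2489 as the highest other, and for resistant against treated sensitive tumours 1 of 100 reached 8760, with 2400. For these 3 the share of splits as large lay under 0.05. Other splits still called up to 6836, 2489 and 2400 probe sets. The share therefore does not exclude other differences among the arrays as a source of calls. The 10 splits of 3 against 3 tumours are too few for a share under 0.05: at 4 h the real count was 34, at 16 h 4727 and for DNA windows 101, with 0 as the highest other each time, and 1 of 10 splits was as large.

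Fewer probe sets differed between resistant tumours and the vehicle tumours of 48 h (441) than with other vehicle tumours. Fewer vehicle arrays do not account for this, because any 2 vehicle tumours of 4 h or of 16 h gave 1191 or more. A component shared by the 48 h and resistant arrays may contribute: across probe sets, the difference of 48 h from 16 h vehicle tumours correlated with that of resistant from 4 h vehicle tumours at r = 0.24, with no array in common, against -0.03 for a control pair. With vehicle tumour 1 of 48 h alone r was 0.29 and with tumour 3 alone 0.1, so it rests mainly on tumour 1. Whether the component is technical, as the actin ratio could reflect, or belongs to harvest time was not tested.

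The tumours at 80 and 160 mg/kg/day share breakpoints. Mixed DNA is argued against in both directions: chromosome 3, lost at 160 mg/kg/day, allows a share of -0.904% of that tumour in the 80 mg/kg/day array where the shared losses need 68.5%, and the chromosome 15 gains at 80 mg/kg/day allow 6.07% in the 160 mg/kg/day array where they need 146%. An artefact of probes or labelling at fixed positions is argued against by the median step at these 10 breakpoints, which was 0.48 and 0.84 in these arrays and 0.08 at 40 mg/kg/day, a tumour that took no part in choosing the segments, as the vehicle tumours did. Whether the array at 160 mg/kg/day holds a vehicle tumour, as its title and source name say, stays open: 0 of the 23 breakpoints of its segments not shared with vehicle tumours lay at a vehicle breakpoint, a low count that this choice of segments builds in, and over all called segments it shared 4 with each vehicle array at the same probe. A common ancestor cell before or during treatment is a biological explanation that was not tested.

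The followed response was larger in resistant tumours at 20 than at 160 mg/kg/day, by 0.964 against 0.274. Most of this lay in the probe sets that had risen, with means of 0.648 against 0.147. Those that had fallen had means of -0.316 against -0.127, and their values overlapped between the doses. In vehicle tumours of 4 h and 48 h the followed response averaged 0.121 and reached 0.502, so that of 0.274 at 160 mg/kg/day lay within their range. Chance assignment of the 5 tumours to the doses cannot be told apart from a dose effect, because the exact two-sided permutation p of 0.1 is the smallest that 10 splits give.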

How the results depend on the processing

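Of 124 alternatives for 12 counts, other than leaving out a tumour, 96 gave a count within 1.5 times the reported one and 28 did not, and no direction of a named probe set or segment turned. All 32 alternatives for the mean of 3 times of the 4 named probe sets kept direction and threshold, but the fall of 1437933_at ranged from -4.021 to -2.303 with the offset. Of 30 for named segments, 21 stayed within the 95% interval of the mean over probes and 9 did not, all with normexp signals. These gave -0.562 and -0.542 for the chromosome 10 and X losses at 40 mg/kg/day, 0.894 and -0.781 for 1 gain and 1 loss at 160 mg/kg/day and, at 80 mg/kg/day, 1.356 and 0.349 for the chromosome 1 gains, -0.162 and -0.155 for the X losses and -0.145 for that of chromosome 10, so the last 3 would not be called. Added after seeing the data were the vehicle subsets of 4 h, of 16 h and without 48 h, array weights, block and autosomes for windows, vehicle-subtracted DNA signals, the value table for named segments, and normexp signals for the common regions. The cause was not tested unless stated.

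Without a mean-variance trend the count was 17 at 4 h and 125 for the 2 doses. Array weights gave 93 at 4 h, 7220 at 16 h, 83 for the doses, 2501 for the difference between 16 h and 4 h, 650 for vehicle tumours and 46 for windows. Fitting only the groups compared, hence fewer arrays, gave 118 at 4 h, 2004 for resistant against vehicle, 0 for the doses, 2006 for 16 h against 4 h and 34 for vehicle tumours. Resistant against vehicle gave 441 with the vehicle of 48 h only, 2029 at 160 mg/kg/day only and 2243 at 20 mg/kg/day only. Equal array medians gave 136 for the doses and 71 for vehicle tumours. Windows gave 0 with normexp signals, 410 at 0.2 Mb and 26 at 5 Mb, where fewer or more windows were tested. Regions gave 84 with normexp signals (72 gains).

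With the replicate number as a block, the count was 117 at 4 h, 2746 at 48 h, 1663 and 2207 for 48 h and 16 h against 4 h, 20 for vehicle tumours and 29 for windows, and it stayed within 1.5 times for the other RNA counts. No block was fitted for the DNA regions, which are called on each array by itself. The numbers did not pair the tumours: deviations of same-numbered tumours correlated at 0.121, 0.04 and 0.145 at 4 h, -0.195, -0.201 and 0.18 at 16 h and -0.095 at 48 h.

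The share of higher calls moved with scaling. Equal array medians gave 32% at 16 h (54.7% reported), 31.8% at 48 h (51.2%), 30.9% for the mean of 3 times (54.2%), 27.7% for resistant against vehicle (60.1%), 30.1% for the doses (15%), 31.3% and 25% for 48 h and 16 h against 4 h (47.7% and 43.2%) and 63.4% for vehicle tumours (84.5%). Quantile normalization gave 40.9% at 48 h, 42.8% for the mean and 46.3% for resistant against vehicle. Normexp gave 85.7% gains among regions (44.4%). The median log2 change of all probe sets moved from 0.093 to -0.051 at 16 h, 0.086 to -0.146 at 48 h, 0.075 to -0.052 for the mean, 0.075 to -0.076 for resistant against vehicle, -0.05 to 0.066 for the doses and 0.051 to -0.174 and 0.064 to -0.072 for the differences, under equal medians. So the balance of rises and falls depends on scaling.

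Leaving out each tumour in turn gave ranges of 2 to 31 at 4 h, 2846 to 4119 at 16 h, 2862 to 6934 at 48 h, 4797 to 7375 for the mean, 1321 to 4405 for resistant against vehicle, 6485 to 9027 against treated, 4 to 1360 for the doses, 1523 to 4507 and 599 to 1296 for the differences, 7 to 113 for vehicle tumours, 32 to 475 for windows and 22 to 56 for regions (22 without the 80 mg/kg/day tumour). A lone tumour left in a group was assumed to vary like the others. Not run were the mean of probe sets of a gene, set tests and expression inside DNA gains, which need gene names, and slide or scan date as a block for the DNA arrays, as no slide held more than 1 array and the 6 had 1 scan day. Scan dates of the RNA arrays were not used here.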

Other observations

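Genes with probes inside changes not shared with vehicle tumours numbered 21 in gains and 772 in losses at 40 mg/kg/day, 744 and 1197 at 80 mg/kg/day and 758 and 981 at 160 mg/kg/day, of 16375 in all. Some apoptosis regulators, not all of which are used here, lay in them: Bcl2l1 and Bcl2l11 in gains at 80 and 160 mg/kg/day, joined by Bcl2 at 160 mg/kg/day, and Bad and Fas in losses in both tumours. Xiap lay in a loss at 40 and 80 mg/kg/day. Of 10 drug efflux transporters, Abcc2 was in a loss at 80 and 160 mg/kg/day and none was in a gain absent from vehicle tumours, while Abcg2 was in a gain on all 6 arrays. No macrophage, endothelial or keratinocyte marker lay in such a change. The Y chromosome had medians of -0.44, -0.37 and -0.59 in the resistant tumours at 40, 80 and 160 mg/kg/day and 0.15, -0.18 and -0.15 in vehicle tumours. The sex of the liver donor is not given in the sources used here.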
